A study of Mus musculus with 4 samples.

How the data were processed

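The measured unit was counts: the deposited matrices hold UMI counts per gene and barcode, written by Cell Ranger 8.0.1 per the file headers, with 33696 genes and no filter on barcodes. Per the submitters' processing notes, reads were processed with Cell Ranger and STAR 2.7.3a on mm10. Per the labels, libraries were made with droplet-based 3′ chemistry from CD8+ T cells sorted from B16-F10 tumours. Of the gene IDs, 1735 are absent from GENCODE mouse release 21 and 52 gene entries share a symbol, so no coordinates are given. Of 382 genes on the fixed lists, 2 were absent from the gene list.

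A barcode was called a cell when its UMIs reached the larger of 1000 and the 99th percentile of the 10000 largest barcodes divided by 10, with at least 500 genes and at most 10% mitochondrial UMIs. This called 8198, 9978, 3917 and 7853 barcodes in WT PShigh, WT PSlow, KO PShigh and KO PSlow. Doublets were scored with Scrublet as held in scanpy 1.11.5. Its automatic threshold marked under 0.5% in every library, so the cells with the highest scores were removed at 0.8% per 1000 cells, which took out 538, 796, 123 and 493 barcodes. Cells were normalised by total, log-transformed and clustered over 2000 variable genes without T cell receptor, immunoglobulin, mitochondrial and ribosomal genes, with 30 principal components, 15 neighbours, Leiden resolution 1 and seed 0, which gave 19 clusters.

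The lists, thresholds, comparisons, gene naming rule and the alternatives were fixed before the data were examined. The rule for naming clusters was set after the data were seen, with markers fixed earlier. A class needed at least 3 markers at a log2 fold of 2 or more in at least 10% of cells. A cluster was CD8 T-like when its Cd3 and Cd8 CPM reached 50% of the median cluster and no other class applied. In 0 of 11 CD8 T-like clusters did another class have more markers among the 10 leading genes. That count took the cytotoxicity, exhaustion, naive, cell cycle and interferon lists as own markers beside the CD8 T cell markers. The CD8 T cell markers alone held 0 of the 10 leading genes in each of these clusters, and another class held 1 in clusters 10, 11 and 13. The CD8 T-like name therefore rests on the Cd3 and Cd8 rule.

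UMIs were summed over the CD8 T-like cells of each library and divided by their total to give CPM, and log2 ratios were taken between libraries. Intervals of levels and shares are exact 95% Poisson for sums and exact binomial for shares and cover counting error only. Cells were not treated as replicates, so no p-values and no counts of changed genes are given. Genes were named when they had at least 50 CPM in the higher library and were in at least 5% of its cells, ranked by the end of the interval nearest 0. T cell receptor and immunoglobulin segments, mitochondrial, ribosomal, haemoglobin, Gm and Rik genes, genes tied to sex and markers of other cell types were left out of the naming. The first 12 in each direction per comparison and 8 for the difference between genotypes were taken, with up to 4 members most apart from each list and a fixed set of T cell genes. List members needed 10 CPM in the higher library. Each list median was placed among 10000 random lists matched in size and in 20 expression bins, and its interval came from 2000 resamples of members. There were 13 state lists and 14 marker lists. The neutrophil, B cell, gamma delta T cell, melanoma, fibroblast, endothelial and mast cell or basophil lists had under 3 measured members in CD8 T-like cells and are not reported.

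The procedure was tested on simulated data. Counts were Poisson draws from a profile shared by both libraries except at the genes set apart, so they held counting error only. The results below therefore check the calculation. They say nothing on variation between animals, libraries or batches, or on genes regulated together. Of genes set 1.5-fold, 2-fold and 4-fold apart, 100% were recovered in the right direction. Intervals held the true value for 95.0%, 95.2%, 94.9% and 95.3% of genes in WT PShigh over PSlow, KO PShigh over PSlow, KO over WT in PShigh and KO over WT in PSlow. Among 200 unchanged lists per comparison, 4.5%, 4.0%, 4.5% and 3.0% fell outside the central 95%.

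Alternatives were other limits on UMIs, genes and mitochondrial share, doublets kept, a per-cell gate, all called cells, TMM factors from edgeR 4.0.16, median-of-ratios factors from DESeq2 1.42.0, the mean of each cell's CPM, thinning to 2000 UMIs, no cycling-like cells, free RNA subtracted, other CPM limits for members and Leiden resolutions of 0.5 and 2. A further 5 were added after the data were seen. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3.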

Results

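CD8+ T cells were sorted from B16-F10 tumours, a transplanted mouse melanoma line, grown in wild-type (WT) mice or in mice labelled CD300ld KO, and profiled by droplet-based 3′ single-cell RNA sequencing. Each genotype was sorted into a PShigh and a PSlow fraction, and each of the 4 groups held 1 library. The sort text pairs PShigh with the lowest and PSlow with the highest staining, against the names of the fractions, so groups here follow the sample titles. The deposited matrices held 172755436 UMIs for WT PShigh, 107900443 for WT PSlow, 112294333 for KO PShigh and 113933870 for KO PSlow. After cell calling and removal of doublets, 7660, 9182, 3794 and 7360 cells remained in the same order, with medians of 14063, 7564, 21257.5 and 8637.5 UMIs per cell. With 1 library per group the difference has no replicate check in any comparison. Intervals of levels, ratios and shares cover counting error only, and those of list medians the spread between list members only.

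Cd300ld, the gene named in the genotype label, encodes a surface receptor of myeloid cells. Over barcodes with more than 200 UMIs its level was 7.30 CPM in WT PShigh (1202 UMIs), 2.38 in WT PSlow (241 UMIs), 10.8 in KO PShigh (1150 UMIs) and 1.09 in KO PSlow (115 UMIs). In macrophage-like cells its level was 30.1 CPM (95% interval 27.8 to 32.6) in WT PShigh and 40.3 CPM (37.8 to 43.0) in KO PShigh. In the PSlow libraries it was 41.7 CPM (36.1 to 48.0) in WT and 23.7 CPM (18.3 to 30.3) in KO. In CD8 T-like cells Cd300ld was low, at 0.853 CPM in WT PShigh, 0.167 in WT PSlow, 1.02 in KO PShigh and 0.230 in KO PSlow, against 7.12, 2.76, 9.83 and 0.281 CPM in the free RNA of the same libraries. In conventional dendritic-like cells Cd300ld stood at 5.7 CPM (3.3 to 9.1, 17 UMIs) in KO PShigh and 15.9 CPM (13.2 to 19.1, 120 UMIs) in WT PShigh. In the PShigh library labelled KO it was therefore lower than in WT in these cells. It was not lower over barcodes with more than 200 UMIs, in macrophage-like cells or in CD8 T-like cells. In the PSlow library labelled KO, Cd300ld was lower than in WT over barcodes with more than 200 UMIs, in macrophage-like cells and in free RNA. It was not lower in CD8 T-like cells there. The PShigh and PSlow libraries labelled KO therefore differ in this check. A 3′ tag outside the deleted part of a gene checks nothing, and which part was deleted is not given in the sources used here, so the genotype labels were kept as given and the libraries are called those labelled KO.

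The first question was which cells each sort contained. CD8 T-like cells made up 73.5% of called cells in WT PShigh (95% exact binomial interval 72.5 to 74.5), 95.3% in WT PSlow (94.8 to 95.7), 69.1% in the PShigh library labelled KO (67.6 to 70.6) and 92.1% in the PSlow library labelled KO (91.4 to 92.7). Macrophage-like cells, which carried C1qa, C1qb and C1qc of the complement C1q complex, formed 16.03% of WT PShigh (15.2 to 16.9) and 24.7% of KO PShigh (23.3 to 26.1). They formed 2.09% of WT PSlow (1.81 to 2.40) and 1.77% of KO PSlow (1.48 to 2.09). Conventional dendritic-like cells were also more frequent in the PShigh libraries, at 5.77% against 0.272% in WT and 3.35% against 1.26% in KO. Plasmacytoid dendritic-like cells went the other way, at 0.574% of WT PShigh, 1.29% of WT PSlow, 1.00% of KO PShigh and 3.87% of KO PSlow. CD4 or Treg-like cells made up 2.35%, 0.174%, 0.975% and 0.693% of the 4 libraries in the same order. Melanoma-like cells made up 0.405% of WT PShigh, 0.659% of KO PShigh and 0.0543% of KO PSlow. They were 0 of 9182 cells of WT PSlow, where the exact interval allows a share of up to 0.0402% in this clustering. Other settings gave 0.1133% (2000 UMIs), 0.8059% (Leiden resolution 0.5) and 0.9321% (doublets kept) in WT PSlow, so absence is not settled. A cluster of 222 cells with T cell and macrophage genes side by side was left unnamed and held 1.38%, 0.926%, 0.264% and 0.285% of the libraries.

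These shares follow a sort for CD8+ T cells and a UMI minimum that differed between libraries (5614.7, 3851.7, 6833.4 and 4593.2 UMIs), and the median depth per cell of the PShigh libraries was higher. With a minimum of 500 UMIs and 200 genes in every library, the CD8 T-like share was 55.6%, 81.5%, 56.3% and 72.9%.

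**Figure D1:**
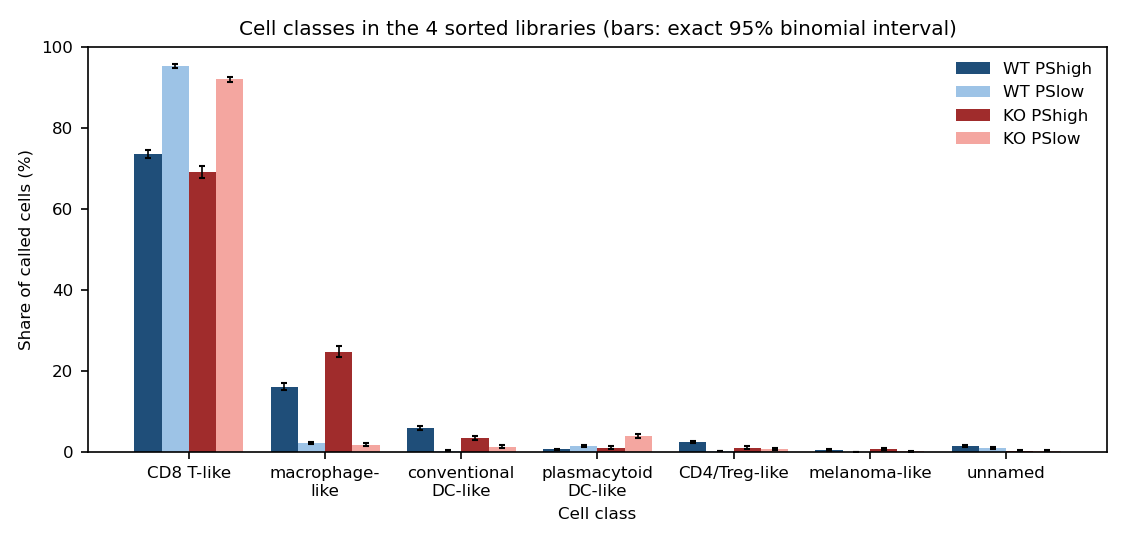
Share of called cells (%) in each cell class for the 4 libraries, with bars at the measured share and error bars at the exact 95% binomial interval. Macrophage-like cells formed 16.03% and 24.7% of the PShigh libraries against 2.09% and 1.77% of the PSlow libraries.

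CD8 T-like cells were clustered again without the genes of the fixed state lists, a choice made after the data were seen, so that list genes did not define the clusters. Cycling-like cells made up 32.3% of CD8 T-like cells in WT PShigh (31.1 to 33.6) and 3.33% in WT PSlow (2.96 to 3.72), and 39.6% in KO PShigh (37.8 to 41.5) and 10.5% in KO PSlow (9.82 to 11.3). Effector-like cells made up 16.8% and 0.983% in WT PShigh and PSlow, and 24.95% and 4.46% in the libraries labelled KO. Terminally exhausted-like cells formed 34.8% of WT PShigh against 7.57% of WT PSlow, and 20.5% of KO PShigh against 12.01% of KO PSlow. Naive or memory-like cells were more frequent in the PSlow libraries, with 46.2% in WT (45.1 to 47.2) and 40.0% in KO (38.8 to 41.2), against 5.67% and 4.54% in PShigh. Interferon-responding-like cells formed 19.2% of WT PSlow (18.4 to 20.1) and 7.497% of KO PSlow (6.88 to 8.15), against 2.97% and 0.343% of the PShigh libraries. The rest stayed unnamed, at 7.46%, 22.7%, 10.0% and 25.5% of the 4 libraries. Each state kept its direction between the sorts in every clustering tried, but the shares themselves depend strongly on the clustering. With the list genes kept, naive or memory-like cells made up 33.1% of WT PSlow, interferon-responding-like cells 6.41% of WT PSlow and 3.25% of KO PSlow, and terminally exhausted-like cells 35.1% of KO PShigh and 15.8% of KO PSlow. Across the other settings the naive or memory-like share of WT PSlow ran from 16.96% to 74.8% and the terminally exhausted-like share of KO PShigh from 5.575% to 34.2%. The gate, the UMI minimum and the depth gap bear on these shares too, since the median was 14124 UMIs per CD8 T-like cell in WT PShigh, 7463 in WT PSlow, 21411 in KO PShigh and 8352.5 in KO PSlow.

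The first expression comparison asked how PShigh CD8 T-like cells differed from PSlow cells in WT mice. PShigh cells carried far more mRNA of Gzmb, Gzmc, Gzmd, Gzme, Gzmf and Gzmg, which encode granzymes, the proteases of cytotoxic granules, but less of Gzma, a gene singled out after its values were seen. Gzme (ENSMUSG00000022156) reached 344 CPM (95% Poisson interval 341 to 348) against 13.5 CPM (12.7 to 14.3), a log2 ratio of 4.67 (4.58 to 4.76). Gzmc (ENSMUSG00000079186) reached 1064 CPM against 48.4 CPM, 22.0-fold higher. Tcf7 (ENSMUSG00000000782), a transcription factor of naive and progenitor T cells, was 10.4-fold lower in PShigh, at 13.0 CPM against 135 CPM. Klf2, a transcription factor that keeps T cells quiescent, was 11.3-fold lower, and Ifit3, an interferon-induced gene, was 9.05-fold lower.

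Under the fixed naming rule, which sets a CPM limit and leaves out haemoglobin genes and markers of other cell types, the genes named as higher in WT PShigh than in WT PSlow were Gzme, Gzmd, Gzmc, Gzmf and Gzmg, with log2 ratios of 4.67, 4.63, 4.46, 3.82 and 3.32. They were followed by the chemokine Ccl9 (3.22), the filopodial myosin Myo10 (3.16), Serpinb9b (3.18), a relative of the granzyme B inhibitor, and the protease inhibitor Serpine2 (2.87). The replication-dependent histone H2ac24 (3.04), Filip1 (2.91) and the MHC class II chain H2-Eb1 (3.01) were also among them. H2-Eb1 stood at 80.7 CPM in these CD8 T-like cells and at 655 CPM in the free RNA of the same library. With free RNA subtracted at the planned estimate, no H2-Eb1 was left in either library. Its ratio of -0.89 at that setting came from a minimum of 3 UMIs per library and gives no direction. The genes named as lower in PShigh were Klf3 (log2 ratio -3.77), Klf2 (-3.50), the TGF-β-induced Pmepa1 (-3.49), Tcf7 (-3.38), Pou6f1 (-3.27), Ifit3 (-3.18), the chemokine receptor Cxcr3 (-3.14), Emb (-3.02), Aff3 (-3.03), the interferon-inducible Ifi208 (-2.93), Fam241a (-2.90) and Slamf6 (-2.78), a receptor of progenitor exhausted cells. Cd8a was at 557 CPM in PShigh and 580 CPM in PSlow.

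Of 20 measured members of the cytotoxicity and effector cytokine list, 12 were at least 1.5-fold higher in WT PShigh, 4 lower and 4 between, with a median log2 ratio of 1.15 (0.26 to 2.30 by resampling members). Perforin (Prf1) was at 883 CPM against 172 CPM, Gzmb at 1783 against 377 and Ifng, the main effector cytokine, at 418 against 92.9, while Gzma had a log2 ratio of -2.45. Of 17 inhibitory receptor and exhaustion genes, 10 were at least 1.5-fold higher, none lower and 7 between, with a median of 0.84. The interval from resampling members, -0.0082 to 1.32, held 0. Havcr2, which encodes the inhibitory receptor TIM-3, was 5.69-fold higher, Tnfrsf9 4.61-fold, Rgs16 3.73-fold and Entpd1 2.76-fold. Pdcd1, which encodes PD-1, had a log2 ratio of 0.87, and Tox, a regulator of exhaustion, 0.30. All 24 cell cycle genes were at least 1.5-fold higher, with a median of 1.83 (1.5995 to 2.0202), among them Rrm2 at 4.95-fold, Tk1 at 4.86-fold and Mki67 at a log2 ratio of 1.98.

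Of 16 naive, memory and progenitor genes, 15 were at least 1.5-fold lower in WT PShigh, with a median log2 ratio of -2.04 (-3.06 to -1.45). S1pr1, the receptor for exit into lymph, was 14.4-fold lower. All 15 measured type I interferon response genes were lower, with a median of -1.85, led by Ifit3, Ifit1 (8.45-fold), Rtp4 (6.18-fold) and Rsad2 (5.92-fold). Within naive or memory-like cells, a setting chosen after the data were seen, the interferon response median turned to 0.19 and Ifit3 to 0.17. Among glycolytic genes 8 of 14 were higher (median 1.04), with Tpi1 at 3.26-fold and Ldha at 2.40-fold. For oxidative phosphorylation, 5 of 25 were at least 1.5-fold higher and the median was 0.46. Endoplasmic reticulum stress genes had a median of 0.67, with 7 of 13 higher, 1 lower and Asns, the asparagine synthetase, at 4.23-fold. These 8 medians lay at the far ends of 10000 random lists of the same size and expression, a description of these libraries and not a test.

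Lists nearer to the middle of that distribution were the early T cell receptor response (median 0.26, 3 of 11 higher and 2 lower, percentile 93.8), programmed cell death (0.27, 6 of 20 higher and 1 lower, percentile 96.6), redox and ferroptosis (0.26, 6 of 18 higher and 1 lower, percentile 94.4) and heat shock and dissociation (-0.021, 3 of 17 higher and 3 lower, percentile 41.2). Il2ra, the interleukin-2 receptor alpha chain, was 3.85-fold higher and the activation marker Cd69 3.14-fold lower. Cdkn1a, which encodes the cell cycle inhibitor p21, was 6.85-fold higher and the death receptor Fas 2.40-fold lower. Genes of phospholipid scrambling and flipping had a median of -0.21 (percentile 22.2), with 2 of 10 higher, 1 lower and 7 between. The flippase gene Atp11b was 2.19-fold lower, and Anxa5 and the scramblase gene Plscr1 were 1.57-fold and 1.55-fold higher.

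Markers of other cell types moved with this comparison. Within CD8 T-like cells, 7 of 9 measured macrophage markers were at least 1.5-fold higher in WT PShigh (median 2.21), and NK markers had a median of 1.37 over 5 genes. All 4 measured CD4 and Treg markers were higher (1.76). These were Il2ra, Tnfrsf4, Capg and Ikzf2 in every comparison, while Cd4 and Foxp3 fell under the CPM limit. Il2ra and Tnfrsf4 are also on the early receptor response list, so the value is no measure of CD4 or Treg content. Erythroid markers (-0.99, 5 genes) and plasmacytoid dendritic cell markers (-1.18, 3 genes) were lower, and the CD8 T cell markers had a median of -0.19. Car2 of the erythroid, Ccr9 of the plasmacytoid and Klra7 of the NK list were among the 10 leading genes of CD8 T-like clusters. Bst2 of the plasmacytoid list is also on the interferon list. The medians of these marker lists are therefore no measure of those cell types either. The erythroid direction rests on few cells: without the top 1% of cells by haemoglobin, haemoglobin stood at 5.73 CPM in WT PShigh and 4.22 CPM in WT PSlow. C1qb stood at 101 CPM in CD8 T-like cells of WT PShigh and at 799 CPM in the free RNA of that library. Most CD8 T-like cells of WT PShigh lay in clusters 4 (36.7%) and 1 (28.8%), and most of WT PSlow in clusters 10 (41.1%), 7 (15.9%), 13 (11.8%) and 12 (11.2%), so the comparison is largely one between different clusters. Scaling by TMM factors would add 0.11 to every WT log2 ratio of PShigh over PSlow and 0.13 to every ratio in the libraries labelled KO, which turns the sign of Cd8a and of the heat shock list in both genotypes; all ratios here are relative to total UMIs.

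**Figure D2:**
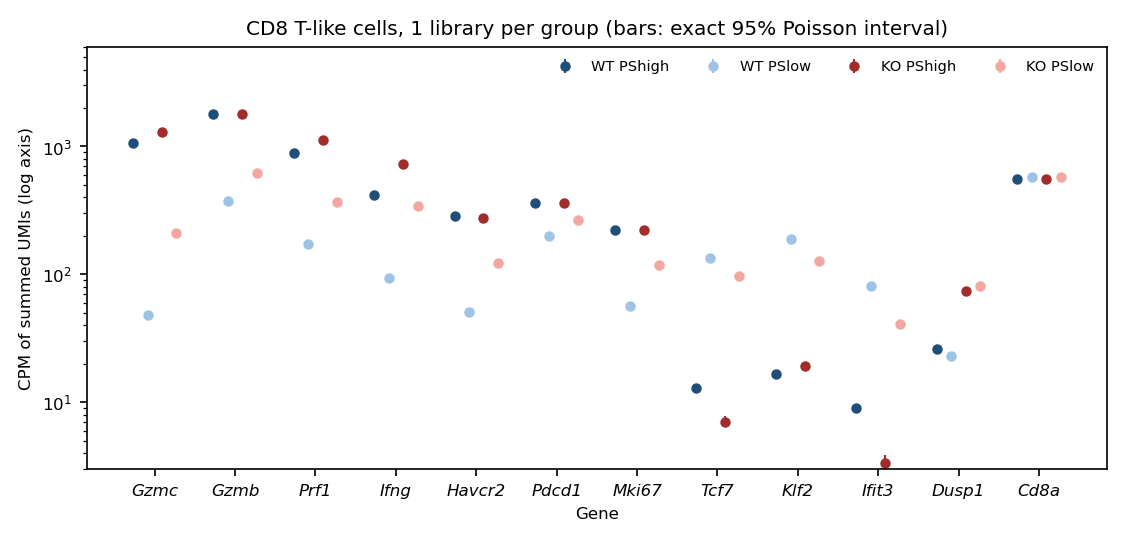
Level of 12 genes in CD8 T-like cells of the 4 libraries, as CPM of summed UMIs on a log axis, with points at the measured level and error bars at the exact 95% Poisson interval, most of them smaller than the points. Gzmc stands at 1064 CPM in WT PShigh and 48.4 CPM in WT PSlow, while Cd8a lies between 556 and 580 CPM in all 4 libraries.

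The second comparison repeated the question in the libraries labelled KO. PShigh cells again carried more mRNA of Gzmb, Gzmc, Gzmd, Gzme, Gzmf and Gzmg, at lower ratios than in WT except for Gzmg, and less of Gzma. Gzme reached 472 CPM (466 to 477) in PShigh against 70.4 CPM (68.6 to 72.3) in PSlow, 6.70-fold higher, and Gzmg 210 CPM against 18.4 CPM, 11.4-fold higher. Tcf7 was 13.7-fold lower in PShigh, at 7.06 CPM against 96.9 CPM, and Ifit3 12.2-fold lower. All 12 genes named as higher and all 12 named as lower in WT were at least 1.5-fold apart in the same direction here. The named sets of both genotypes shared 7 higher genes (Ccl9, Gzmc, Gzmd, Gzme, Gzmf, Gzmg and Serpinb9b) and 8 lower genes (Aff3, Cxcr3, Emb, Fam241a, Klf3, Pmepa1, Slamf6 and Tcf7).

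The genes named as higher by the same rule were Gzmg (log2 ratio 3.51), Gzme (2.74), Gzmd (2.72), Gzmc (2.60), Ccl9 (2.64), Gzmf (2.45), Serpinb9b (2.27), the secreted phosphoprotein Spp1 or osteopontin (1.80), Cdkn1a (1.80), AA467197 (1.73), Prf1 (1.62) and Gzmb (1.54). Those named as lower were Tcf7 (-3.78), Klf3 (-3.78), Cxcr3 (-3.60), Aff3 (-3.58), Pmepa1 (-3.15), the gut-homing integrin chain Itgb7 (-2.98), the transcription factor Lef1 (-2.96), Emb (-2.94), Slamf6 (-2.88), Fam241a (-2.87), Cd7 (-2.82) and Fgf13 (-2.81). Cd8a differed by -0.05 and Cd3e, a chain of the T cell receptor complex, by -0.14.

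Of 21 cytotoxicity genes, 10 were at least 1.5-fold higher in KO PShigh, 3 lower and 8 between (median 0.57, 0.13 to 1.45), with Gzma 5.98-fold lower. Of 17 exhaustion genes 5 were higher and 1 lower (median 0.25, percentile 96.5, inside the middle 95% of random lists), with Havcr2 at 2.25-fold and Tnfrsf9 at 2.07-fold. Pdcd1 had a log2 ratio of 0.45 and Tox of -0.06. Cell cycle genes had a median of 0.87 (0.72 to 1.03), with 21 of 24 higher and Mki67 at 0.90. Naive and progenitor genes had a median of -2.08, with 15 of 16 lower and S1pr1 14.0-fold lower. All 13 measured interferon response genes were lower, with a median of -1.77.

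Glycolytic genes had a median of 0.59, with 7 of 14 higher, and endoplasmic reticulum stress genes a median of 0.46, with 5 of 13 higher and 1 lower. Oxidative phosphorylation genes had a median of 0.32, with all 25 between the 1.5-fold limits. Redox genes had a median of 0.25 (-0.017 to 0.50, an interval that held 0), with 3 of 18 higher, 1 lower and the haem oxygenase gene Hmox1 at 2.96-fold. Medians for programmed cell death (0.10, 4 of 20 higher and 1 lower), early receptor response (-0.013, 2 of 11 higher and 2 lower), heat shock (-0.09, 2 of 18 higher and 3 lower) and phospholipid scrambling and flipping (-0.32, 2 of 10 lower) fell inside the middle 95% of random lists. Atp11b was 2.04-fold lower in this comparison too.

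Within these CD8 T-like cells, macrophage markers were higher in PShigh (median 2.85, 7 of 9 genes), as were CD4 and Treg markers (1.00), NK markers (0.76) and conventional dendritic cell markers (0.71, 3 genes). Irf8, on the conventional dendritic list, stood at 337 CPM in CD8 T-like cells of KO PShigh, above the 262 CPM in the free RNA of that library. Plasmacytoid dendritic cell markers had a median of -0.73, erythroid markers of 0.23 and CD8 T cell markers of -0.21. Most cells of KO PShigh lay in clusters 1 (35.3%), 4 (25.6%) and 2 (15.03%), and most of KO PSlow in clusters 7 (22.3%), 10 (19.8%), 13 (16.3%) and 4 (12.8%). The early receptor response median turned to 0.11 under TMM factors. The exhaustion median turned to -0.09 after subtraction of free RNA at the planned estimate, but that estimate put the free RNA share at 72.1% in KO PSlow and 10.3% in KO PShigh. In KO PSlow it rests in part on Hbb-bs, Irf8, Ighm and Ccr2, which stood at 61.2%, 84.997%, 83.0% and 108% of their free RNA level, against 9.34% for Lyz2, so it probably overstates the share. At the lowest marker ratio, chosen after the data were seen, the exhaustion median was 0.27. Thinning every cell to 2000 UMIs gave cytotoxicity and cell cycle medians of 0.92 and 1.31.

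The third comparison set the library labelled KO against WT within the PShigh sort. Heat shock, early receptor response, cytotoxicity, glycolysis and redox genes had list medians above the middle 95% of random lists, and naive and interferon response genes below it. The intervals from resampling members held 0 for the cytotoxicity, glycolysis, redox and naive lists. Penk, which encodes proenkephalin, stood at 74.6 CPM (72.5 to 76.7) in the library labelled KO and 23.5 CPM (22.5 to 24.4) in WT, 3.18-fold higher. Dusp1, an immediate early phosphatase, stood at 74.3 CPM against 26.2 CPM and Ifng at 731 CPM against 418 CPM. Cd5, a brake on T cell receptor signalling, was 2.32-fold lower, at 71.4 CPM against 166 CPM. Cd300ld itself was not lower in CD8 T-like cells of this library labelled KO, and its 3′ tag neither shows nor excludes loss of the gene.

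The genes named as higher in the library labelled KO by the same rule were Penk (log2 ratio 1.67), the calcium pump Atp2b2 (1.58), Dusp1 (1.503), Spp1 (1.41), the chemokine Ccl1 (1.40), Zc3h12c (1.20), the histone H3c3 (1.18), the stress gene Gadd45b (1.15), Fos (1.13), Gzmg (1.02), Serpinb9b (0.99) and Pcyt1a (0.92), an enzyme of phosphatidylcholine synthesis. Those named as lower were Cd5 (-1.22), Cd6 (-1.13), Fgf13 (-1.11), the sialyltransferase St3gal6 (-1.04), BE692007 (-0.96), Pkp3 (-0.94), Scml4 (-0.90), H2ac24 (-0.88), H2-Eb1 (-0.84), the phosphatase Ptprj (-0.80), Lax1 (-0.80) and Slc9a9 (-0.78). The direction of H2-Eb1 is not settled, since its ratio was 0.045 with free RNA subtracted at the lowest marker ratio. The planned estimate left no H2-Eb1 in WT, so the ratio of 5.75 there is one to the minimum of 3 UMIs. Penk, Atp2b2, Ccl1 and Zc3h12c were among the 10 leading genes of 1 terminally exhausted-like cluster, found with the list genes kept. This cluster held 594 of 2621 CD8 T-like cells in KO PShigh and 523 of 5629 in WT PShigh. Another terminally exhausted-like cluster held 326 and 1793 cells. Cluster shares and levels within the cells of a cluster were not told apart in these ratios.

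Heat shock and dissociation genes had a median of 0.31 (0.15 to 0.89), with 8 of 18 at least 1.5-fold higher and none lower, led by Dusp1, Hspa1a (2.81-fold), Hspa1b (2.58-fold) and Atf3 (2.22-fold). Early receptor response genes had a median of 0.35, with 2 of 11 higher, Tnfrsf4 at 1.99-fold and Nr4a3 at 1.59-fold. Cytotoxicity genes had a median of 0.25 (-0.16 to 0.40), with 3 of 21 higher and 2 lower, Xcl1 at 1.79-fold higher and Gzmk 1.64-fold lower. The cytotoxicity median turned to -0.21 within terminally exhausted-like cells and to -0.11 within naive or memory-like cells, settings chosen after the data were seen. Naive and progenitor genes had a median of -0.40 (-0.68 to 0.13), with 5 of 13 lower and the lymph node homing receptor Ccr7 as the 1 gene higher (2.45-fold). The naive and progenitor median turned to 0.0014 within cycling-like and 0.17 within naive or memory-like cells. Interferon response genes had a median of -0.41 (-0.69 to -0.18), with 4 of 9 lower, among them Mx1 at 2.26-fold lower.

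No member of the cell cycle list (median 0.011, 24 genes), of glycolysis (0.12, 14 genes), of oxidative phosphorylation (0.07, 25 genes) or of phospholipid scrambling (-0.11, 10 genes) was 1.5-fold apart. Exhaustion genes had a median of -0.05 with 1 of 17 lower, programmed cell death 0.04 with 1 of 19 higher and 1 lower, redox 0.09 with 1 of 18 higher, and endoplasmic reticulum stress -0.04 with 1 of 13 higher. Gzmb (log2 ratio 0.0075), Pdcd1 (0.0017), Mki67 (0.0082) and Cd8a (-0.0018) stood at nearly the same level in both libraries, and Havcr2 differed by -0.07. Of the marker lists within CD8 T-like cells, erythroid markers were 8.70-fold higher at the median (log2 3.12, 4 genes), macrophage markers had a median of -0.28, NK markers -0.49, CD4 and Treg markers 0.33 and CD8 T cell markers -0.09. With all called cells in place of CD8 T-like clusters the cytotoxicity median was 0.03 and the naive and progenitor median -0.16, and with a per-cell gate on Cd3 and Cd8 they were 0.02 and -0.16.

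**Figure D3:**
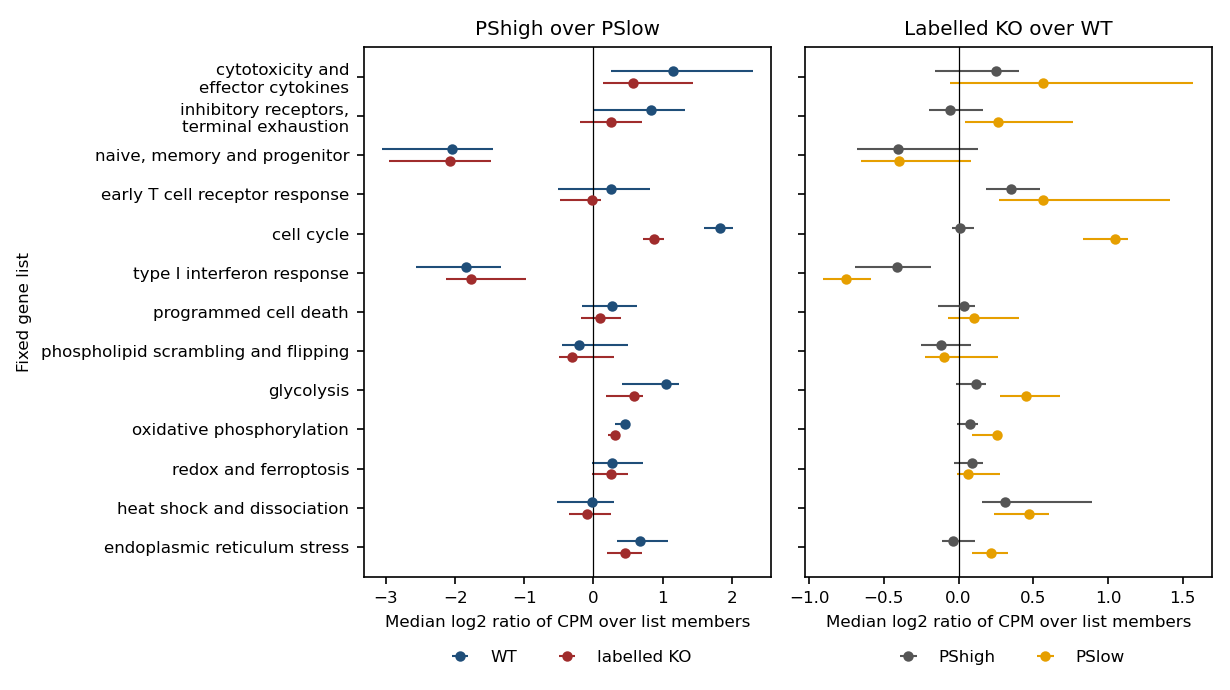
Median log2 ratio of CPM over the members of each fixed list in CD8 T-like cells, for PShigh over PSlow (left, WT and labelled KO) and for labelled KO over WT (right, PShigh and PSlow), with points at the median and lines at the 95% interval from resampling members. The cell cycle list stands at 1.83 in WT and 0.87 in the libraries labelled KO on the left, and at 0.011 in PShigh and 1.04 in PSlow on the right.

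The fourth comparison set the library labelled KO against WT within the PSlow sort, where the cell cycle, cytotoxicity, exhaustion and interferon lists stood further from 0 than in PShigh. Gzmd stood at 101 CPM (98.4 to 103) in the library labelled KO and 16.6 CPM (15.7 to 17.6) in WT, 6.05-fold higher. Gzmc stood at 212 CPM against 48.4 CPM, Ifng at 340 CPM (336 to 344) against 92.9 CPM (90.74 to 95.03) and Mki67 at 119 CPM against 56.1 CPM. The interferon-inducible GTPase gene Iigp1 was 2.46-fold lower, at 37.4 CPM against 92.1 CPM. Cd300ld stood at 0.230 CPM against 0.167 CPM in these cells, from 18 and 13 UMIs, too few to check the label.

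Named by the fixed rule as higher in the library labelled KO were Gzmd (log2 ratio 2.60), Ccl1 (2.49), Gzme (2.38), Spp1 (2.23), Myo10 (2.20), Gzmc (2.13), Ifng (1.87), the chemokine Ccl3 (1.83), Dusp1 (1.83), the linker histone H1f5 (1.82), Gzmf (1.77) and the adhesion molecule Dscam (1.72). Named as lower were Iigp1 (-1.30), Ifit1bl1 (-1.22), Rasgef1b (-1.15), Gvin1 (-1.11), BE692007 (-1.10), Gvin2 (-1.08), Igtp (-1.02), Gbp2 (-1.01), Ifit3 (-0.98), Clec2d (-0.97), Pou6f1 (-0.96) and Ly6c2 (-0.95), of which Iigp1, Gvin1, Gvin2, Igtp and Gbp2 belong to the interferon-inducible GTPases. Ccl1, Dusp1 and Spp1 were named as higher, and BE692007 as lower, in the library labelled KO in both sorts. The terminally exhausted-like cluster led by Ccl1 and Penk also had Dscam among its 10 leading genes. It held 610 of 6776 CD8 T-like cells in KO PSlow and 187 of 8746 in WT PSlow, so cluster shares enter these ratios too.

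Of 24 cell cycle genes, 21 were at least 1.5-fold higher and none lower (median 1.04, 0.83 to 1.13), with Ube2c at 2.697-fold and Cdk1 at 2.47-fold. The cell cycle median was 0.72 without cycling-like cells and 0.21 within naive or memory-like cells. Of 20 cytotoxicity genes, 10 were higher and 1 lower, with a median of 0.56 (-0.056 to 1.57). This interval held 0, and the median was -0.077 within terminally exhausted-like cells. Prf1 and Gzmb had log2 ratios of 1.09 and 0.71. Of 17 exhaustion genes 6 were higher and none lower (median 0.27), with Rgs16 at 3.19-fold, Tnfrsf9 at 2.96-fold and Havcr2 at 2.41-fold. Pdcd1 had a log2 ratio of 0.42 and Tox of 0.16. Early receptor response genes had a median of 0.56 with 5 of 11 higher, among them Tnfrsf4 at 3.61-fold and Nr4a3 at 2.85-fold. Interferon response genes had a median of -0.76 (-0.91 to -0.59), with 12 of 15 lower and none higher. Naive and progenitor genes had a median of -0.40 (-0.65 to 0.086, an interval that held 0), with 5 of 16 lower, Tcf7 at -0.48 and Ccr7 1.77-fold higher.

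Heat shock and dissociation genes had a median of 0.47 (0.24 to 0.60), with 5 of 17 higher and Fos at 2.09-fold and Jun at 1.85-fold. Glycolytic genes had a median of 0.45 with 6 of 14 higher, oxidative phosphorylation genes 0.26 with none of 25 apart by 1.5-fold, and endoplasmic reticulum stress genes 0.22 with 1 of 13 higher. Programmed cell death (0.11, 3 of 19 higher), redox (0.07, 1 of 17 higher) and phospholipid scrambling and flipping (-0.10, none of 10 apart by 1.5-fold) fell inside the middle 95% of random lists. Within CD8 T-like cells, erythroid markers had a median of 1.80, CD4 and Treg markers 1.12, macrophage markers -0.29, NK markers -0.12, plasmacytoid dendritic cell markers -0.05 and CD8 T cell markers -0.16. Without the top 1% of cells by haemoglobin, haemoglobin stood at 35.8 CPM in the library labelled KO and 4.22 CPM in WT, further apart than the erythroid median. Within naive or memory-like cells the exhaustion median turned to -0.19 and the naive and progenitor median to 0.32. Subtraction of free RNA at the planned estimate, 39.8% in WT PSlow and 72.1% in KO PSlow and probably too high in both, turned the naive and progenitor median to 0.0062 and the heat shock median to -0.11, and gave a cell cycle median of 0.50. It also turned oxidative phosphorylation to -1.58, endoplasmic reticulum stress to -0.12 and Ccl1 to -4.35. At the lowest marker ratio the values were -0.39 for naive and progenitor, 0.44 for heat shock, 1.05 for cell cycle and 2.54 for Ccl1, and the oxidative phosphorylation and endoplasmic reticulum stress medians kept their direction. Thinning to 2000 UMIs gave a naive and progenitor median of -0.08.

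The last comparison asked whether the PShigh to PSlow ratio differed between genotypes, as the ratio in the libraries labelled KO minus that in WT. The cell cycle list had a median difference of -0.96 (-1.03 to -0.82), with 21 of 24 genes at least 1.5-fold lower. The cytotoxicity list had a median of -0.54 (10 of 21 lower, 1 higher), the exhaustion list -0.47 (7 of 17 lower), glycolysis -0.43 (2 of 14 lower) and the early receptor response -0.37 (4 of 11 lower). The interval of the early receptor response, -0.84 to 0.031, held 0. For Mki67 the genotypes stood apart in PSlow, at 119 CPM in the library labelled KO and 56.1 CPM in WT, and together in PShigh, at 222 and 221 CPM.

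Among genes the naming rule admits, the difference was lowest for Filip1 (-2.03), H2ac24 (-2.03), H2-Eb1 (-2.02), Gzme (-1.93), Gzmd (-1.91), Gzmc (-1.86), Myo10 (-1.84) and the MHC class II gene H2-Aa (-1.71). It was highest for Hdgfl3 (1.37), Rasgef1b (1.24), Ccnd2 (1.12), which encodes cyclin D2, Rnaset2b (1.09), Rnaset2a (1.01), Tanc2 (0.86), Hspa1b (0.83) and Klf2 (0.75). H2-Aa stood at 89.6 CPM in CD8 T-like cells of WT PShigh and at 750 CPM in its free RNA. The place of H2-Eb1 is not settled, since its PShigh levels depend on free RNA. Its ratio of KO over WT in PShigh was 0.045 with free RNA subtracted at the lowest marker ratio. Rnaset2a and Rnaset2b, Hspa1a and Hspa1b, Gvin1 and Gvin2, and the histone genes are close copies, so their separate values are uncertain.

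Lists with a difference nearer to 0 were naive and progenitor (median -0.03), interferon response (0.13, 1 of 15 higher), programmed cell death (-0.14, 2 of 20 lower), phospholipid scrambling and flipping (-0.13), oxidative phosphorylation (-0.11), redox (-0.05, 1 of 18 higher), heat shock (-0.05, 2 of 18 higher) and endoplasmic reticulum stress (-0.15, 1 of 13 lower). Of the marker lists, erythroid markers had a difference of 1.11, CD4 and Treg markers -0.74, NK markers -0.64, conventional dendritic cell markers -0.63, plasmacytoid dendritic cell markers 0.35, macrophage markers 0.11 and CD8 T cell markers 0.05. The erythroid value rests on few cells, since without the top 1% haemoglobin stood at 35.0 CPM in PShigh and 35.8 CPM in PSlow of the libraries labelled KO, and at 5.73 and 4.22 CPM in WT, which turns the sign of the difference. After subtraction of free RNA the cell cycle difference was -0.10 at the planned estimate, which is probably too high in the PSlow libraries, and -0.98 at the lowest marker ratio. The interferon difference turned to -0.12 with each cell weighted alike and to -0.05 with cells thinned to 2000 UMIs.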

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

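H2-Eb1 and the histone H2ac24 lay on opposite sides of WT in the 2 sorts. H2-Eb1 had a log2 ratio of the library labelled KO over WT of -0.84 in PShigh and 1.18 in PSlow, and H2ac24 of -0.88 and 1.15. The difference between the sorts was not tested. Free RNA of the PShigh libraries held H2-Eb1 at 420 CPM in KO and 655 CPM in WT, the same direction as the cells. With free RNA subtracted at the lowest marker ratio, the H2-Eb1 ratio of KO vs WT in PShigh was 0.045, so its direction in PShigh CD8 T-like cells is not settled. The planned estimate left no H2-Eb1 in WT PShigh, so the ratio of 5.75 there is one to the minimum of 3 UMIs. H2ac24 has close copies, so its level is uncertain.

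Barcodes of at least 500 UMIs with more than 20% mitochondrial UMIs were left out of every result except the Cd300ld level over barcodes with more than 200 UMIs. They made up 7.35% of such barcodes in WT PShigh and 6.65% in KO PShigh, against 1.88% in WT PSlow and 2.27% in KO PSlow, and the difference was not tested.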

How the results depend on the processing

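No paired analysis was possible because the labels give no replicate numbers and the results come from no test. An additive model of sort and genotype over the 4 libraries was possible, with 1 residual degree of freedom, and was not fitted, since its only error is the difference between genotypes reported here. With 1 library per group no replicate could be left out. Of 300 values of the main list medians under settings fixed beforehand, 277 stayed, 22 moved and 1 reversed, and of 80 under settings chosen after seeing the data 47 stayed, 22 moved and 11 reversed. Of 28 values of CD8 T-like shares 20 stayed and 8 moved, and of 1248 values of named genes under settings fixed beforehand 619 stayed, 626 moved and 3 reversed. Of 252 values of other shares under settings fixed beforehand 131 stayed and 121 moved, and of 20 chosen after seeing the data 1 stayed and 19 moved. In what follows, A is WT PShigh over PSlow, B the same in KO, C is KO over WT in PShigh, D in PSlow, and E is B minus A. The cause was not tested for any shift.

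At 500 UMIs and 200 genes CD8 T-like shares were 55.6% (WT PShigh), 81.5% (WT PSlow), 56.3% (KO PShigh) and 72.9% (KO PSlow). With doublets kept they were 70.1% in WT PShigh, 67.1% in KO PShigh and 91.4% in KO PSlow, and at Leiden resolution 2 71.9% in WT PShigh. Cell cycle medians were 0.68 (B) and -0.045 (C) with all called cells and 0.70 (B) with the per-cell gate. With the mean of each cell's CPM they were 2.24 (A), 1.31 (B) and 0.15 (C), with naive -0.26 and interferon -0.12 in E. Thinned, they were 2.13 (A), 1.31 (B), 0.16 (C) and -0.80 (E), with interferon -0.045 in E. Without cycling-like cells they were 1.49 (A), 0.71 (B) and 0.72 (D), with naive -0.25 and interferon -0.15 in E.

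With free RNA subtracted, cell cycle was 2.10 (A), 2.20 (B), 0.50 (D) and -0.10 (E). Naive was -3.05 (B), 0.0062 (D) and -0.585 (E), exhaustion -0.97 (E) and interferon -0.17 (E). In D, oxidative phosphorylation was -1.58, heat shock -0.11, endoplasmic reticulum stress -0.12 and Ccl1 -4.35. H2-Eb1 was -0.89 (A) and 5.75 (C), and 0.045 (C) at the lowest marker ratio, an alternative chosen after seeing the data. The -0.89 and 5.75 were set by the minimum of 3 UMIs, since the planned estimate left no H2-Eb1 in WT PShigh or WT PSlow.

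The last 3 settings were chosen after seeing the data. Their cells come from the clustering that kept the list genes and were named by these lists, so a list's value within the state it names says little. In terminally exhausted-like cells, exhaustion was -0.062 (A) and -0.085 (E), naive -0.58 (A) and -0.49 (B), cell cycle 0.79 (A), 0.29 (B), 0.17 (C), 0.74 (D) and -0.56 (E), cytotoxicity -0.21 (C) and -0.077 (D), interferon -0.040 (E) and Rasgef1b 0.45 (D). In cycling-like cells, naive was -1.20 (A), -0.96 (B), 0.0014 (C) and 0.27 (E), cell cycle 0.024 (A), -0.0048 (B), -0.045 (C), -0.070 (D) and 0.053 (E), endoplasmic reticulum stress -0.14 (D), exhaustion -0.22 (E) and Rasgef1b 0.094 (D). In naive or memory-like cells, naive was -0.055 (A), -0.050 (B), 0.17 (C) and 0.32 (D), cell cycle 0.78 (A), 0.30 (B), -0.27 (C), 0.21 (D) and -0.59 (E), and interferon 0.19 (A) and -0.59 (E). Cytotoxicity was -0.11 (C), redox -0.018 (C), exhaustion -0.19 (D) and -0.26 (E), oxidative phosphorylation -0.044 (D) and endoplasmic reticulum stress -0.076 (D). AA467197 was -0.14 (B), Aff3 0.12 (B) and 0.27 (A), Cd7 0.15 (B), Emb 0.16 (B), Ifit3 0.17 (A) and 0.10 (D), and Pmepa1 0.061 (B).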

Other observations

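Macrophage-like cells of the PShigh libraries also differed by genotype label. Heat shock and dissociation genes had a median log2 ratio of 0.53 in the library labelled KO over WT, with 8 of 18 at least 1.5-fold higher, among them Hspa1b, Hspa1a, Fosb and Dusp1. Interferon response genes had a median of -0.48, with Zbp1, Irf7 and Oasl2 among the 6 of 18 that were lower; free RNA was not subtracted from this value. Most haemoglobin UMIs of CD8 T-like cells came from few cells: the top 1% held 89.5% in WT PShigh, 96.1% in WT PSlow, 92.7% in KO PShigh and 91.0% in KO PSlow. Without those cells haemoglobin still stood at 35.0 CPM in KO PShigh against 5.73 CPM in WT PShigh. In PSlow it stood at 35.8 CPM in KO against 4.22 CPM in WT. The gap was not confined to CD8 T-like cells. Macrophage-like cells held 57.1 CPM in KO PShigh against 11.7 in WT PShigh, and 42.6 in KO PSlow against 4.28 in WT PSlow. Both dendritic-like classes went the same way, from few UMIs in WT. Free RNA held 203 CPM in KO PShigh against 50.039 in WT PShigh, and 519 in KO PSlow against 106 in WT PSlow. Whether free RNA accounts for the gap was not tested.

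The tests on macrophage-like cells in the PShigh libraries were chosen only after the result was seen. If droplets with free RNA alone had been called, CD8 T cell markers would stand near their free RNA level, but their median ratio to it was 0.2025 in WT and 0.255 in KO, which rules this out as the source. Cells with CD8 T cell markers at 25% or more of the CD8 T-like median made up 14.9837% in WT and 17.094% in KO, so T cell and macrophage doublets could be part but not all of this class. Binding of the sort reagents to macrophages was not tested and stays open.

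The tests on the difference between the PSlow libraries were chosen only after the result was seen. With cells thinned to 2000 UMIs the cell cycle median was 1.0338, so a larger weight of deeper cells in the sums is excluded as the source of the cell cycle value. The naive and progenitor median shrank on thinning, as given above, so for that list such a weight is not excluded. Thinning followed cell calling and clustering, so depth acting through the UMI minimum or the cell classes was not tested by it. A larger part of cells of the kind sorted as PShigh could account for the cytotoxicity, exhaustion, naive, cell cycle and glycolysis lists, whose member intervals overlap from 36.9362% to 41.9997% of UMIs from WT PShigh cells, a smaller share of cells since these hold more UMIs each, but this is weak: the shares were 19.8%, 36.7%, 31.2%, 38.7% and 42.7%, from 16, 10, 15, 24 and 9 members, and the naive interval (-19.4% to 44.7%) excludes little. The interferon list would need 60.031% (48.2% to 69.7%), outside the overlap. Whether the gate or the genotype lies behind such a mixture was not tested.

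Of the tests on the heat shock list, higher in both libraries labelled KO, the one on macrophage-like cells was written before its result and those on a mixture and on free RNA were chosen only after the result was seen. A mixture of the summed CD8 T-like profiles of the WT libraries is excluded for the list, since 52.9412% of 17 members stood above both WT libraries in KO PSlow. A shift between cell states is not excluded by this, since it can put a gene above both sums, and was not tested. At the 5% mitochondrial limit, 1 state cluster had Hspa1a and Hspa1b among its 10 leading genes. It held 446 of 6703 CD8 T-like cells in KO PSlow and 93 of 8660 in WT PSlow. Handling of the tumours would act on every cell type, and the list was higher in macrophage-like cells too, with a median of 0.5327, so handling may account for it. Free RNA shared by the droplets is excluded as the source in macrophage-like cells, whose median was 0.7258 (0.37 to 1.27) with free RNA subtracted. Library batch and genotype cannot be told apart here, and the genotype stays open.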
